A study of Mus musculus with 8 samples.

How the data were processed

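The series comprises 8 samples of total RNA from whole mouse embryos at embryonic day 9.0, 4 from wild-type and 4 from Arid3b-null embryos, each a pool of 3 to 4 embryos. Groups and replicate numbers were taken from the labels. Whether the pools came from separate litters is not given there, and p-values measure the spread between these pools. Per the file headers, each array is a 1-colour whole mouse Agilent design, scanned and read by Feature Extraction 9.5.3.1. Per the file headers, the processed intensity of each spot is the Cy3 brightness after subtraction of a fitted spatial background and detrending within the array, with surrogate values for dim spots, and nothing was scaled between arrays. The deposited mean spot intensity and median local background intensity were used only for an alternative background correction. The deposited value table of the series holds log2 values for 27108 probes, with column medians of 9.44 to 9.47. How it was made is not given in the sources used here. All its probe names matched, and each column correlated with the log2 processed signal at 0.988 or more. Differences between null pool 1 and wild-type pool 1 correlated at 0.955 with those of quantile-normalized signals, so that direction is settled. Correlations do not settle the scale. In wild-type pool 1 the slope of the table's values on quantile-normalized log2 signals was 0.893 over kept probes, near a log2 scale but somewhat compressed. All columns share the lowest value of 5.66 and the highest of 18.8, and the added constant and the background correction stay unknown.

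Each array holds 45018 spots, of which 1639 are controls. Control spots and spots with a non-uniformity or population outlier flag were left out, 87 to 175 per array. Spots of the same probe were averaged on the log2 scale, which gave 41174 probes. Each array's 75th percentile was subtracted. Probes well above background on at least 4 of the 8 arrays, whatever their group, were kept (25555 probes), and a probe was taken as above background where at least 0.5 of its spots were. Names were updated through a RefSeq table for assembly GRCm38.p6, from which no coordinate was used. Of all probes 22951 were named by accession, 6659 by symbol and 3109 by a unique older name, and 8455 kept the name in the file. Coordinates are those of the files, on mm7. The brightest kept probe stood for each gene, and at least 2 values per group were required, a rule added when the files were examined, which left 17099 genes. Of 242 called genes with several kept probes, 215 had all of them in the same direction.

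Groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on the log2 values with genotype as the only term, and Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05 with no minimum fold. Folds are ratios of geometric means of the signal. For a probe not well above background on any array of a group, only a bound was given. The 33 gene lists were fixed before the data were examined and tested with camera, two-sided, with a preset correlation between genes of 0.01, and adjusted over the lists. With an estimated correlation camera called 0 of them, with 5 at an unadjusted p under 0.05, against 12 with the preset value. Fry and an exact permutation test of the list mean per array were also run. Camera, fry and the list means used members with a value on all 8 arrays, which left out 5 genes in 5 lists, a rule set for the list means after their first values were seen. The exact test within same-numbered pairs was also chosen after the data were seen. Members were counted over all genes tested and adjusted over the list alone. Calls near Arid3b were compared with Fisher's exact test. The genes named are Arid3b, the 12 called genes with the largest rise and the 12 with the largest fall whose groups do not overlap, leaving out clone, predicted and accession names, and per list up to 4 called members with the smallest adjusted p, or the member with the smallest p where none was called. Further list members were named as examples after their values were seen. Some genes that this rule takes are not reported here.

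The steps were tested on simulated data with the real means and spreads of 17002 genes. Of 50 genes changed 1.5-fold, 100 changed 2-fold and 50 changed 4-fold, limma recovered 54.0%, 78.0% and 88.0%, and 8 of 157 calls (5.10%) were false. A planted list was recovered, and 0 of the unchanged lists passed. The noise was drawn independently for each gene and array. The simulation therefore does not test lists of correlated genes, or the structure of slides and pairs.

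Pools with the same number deviated from their group means together, with correlations across genes of 0.557, 0.635, 0.523 and 0.426 for numbers 1 to 4, so the numbers were taken to pair the samples and fits with the number as a block are given where they change a call. The numbers are nested in the slides. With each slide's mean removed the correlation was 0.518 on slide 1 and 0.0981 on slide 2. Wild-type pool 4 deviated most like a null pool of another number, at 0.496. Scan and slide coincide, so that no separate fit with the scan was made. The alternatives were normexp background correction, quantile, median and other scalings, other filters on dim probes, the mean of a gene's probes, the deposited value table, other variance models, blocks for replicate number and slide, each pool left out, and other thresholds and set tests. Fits within each slide, with the level of Y-linked transcripts as a covariate, and without genes near Arid3b were added after the data were seen. Fits with a block or covariate and other splits of the arrays used only genes with a value on all 8 arrays, where the groups as labelled gave 712 called genes in place of 718.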

Results

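Whole mouse embryos at embryonic day 9.0 were profiled on 8 one-colour Agilent arrays. The 4 wild-type samples and the 4 samples from embryos lacking Arid3b each held the total RNA of 3 to 4 embryos. Arid3b encodes a DNA-binding protein of the AT-rich interaction domain family, and the comparison asks which transcripts differ in embryos without it. Between 60.0% and 64.1% of probes were well above background on each array, and the 75th percentile of the processed signal lay between 1280 and 1703. No probe was saturated on any array. The number of arrays limits the precision of every value below. Pools 1 and 2 of each group were hybridised on slide 1 and pools 3 and 4 on slide 2. On both slides the wild-type pools took positions 1 and 2 and the null pools positions 3 and 4, so position on the slide and genotype cannot be told apart. Values are log2 signals relative to each array's 75th percentile, given as mean ± SD with n = 4 pools per group, and differences are null minus wild type with the standard error of the limma fit.

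The pools also differed in embryo sex. The X-inactivation transcript Xist was not well above background in wild-type pool 2 or in null pools 2 and 4. The Y-linked Eif2s3y was not well above background in wild-type pools 1 and 4. The remaining 3 pools carried both signals. The level of Y-linked transcripts, relative to the highest pool for each, was 0.0238, 0.788, 0.25 and 0.0267 in wild-type pools 1 to 4. In null pools 1 to 4 it was 0.485, 0.791, 0.637 and 1, so the null pools leaned to male. No member of the list of 5 sex-linked transcripts was called between the groups, and the list's camera adjusted p was 0.0845. The list sets Xist beside Y-linked genes, which mark opposite sexes, so this test cannot show that sex was balanced. The smallest p in the list was that of Uty, with a limma adjusted p of 0.175. Its signal was well above background in 1 of 4 wild-type and 3 of 4 null pools, so that no size of difference is given. Without wild-type pool 2 the list's camera adjusted p was 0.00804, with the null pools higher, and without wild-type pool 3 it was 0.0454. The list also passed with a median shift (0.00559), with no shift between arrays (0.00797) and with the deposited value table (0.0448).

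Arid3b was lower in all 4 null pools on each of its 3 probes, which lie next to each other on chromosome 9 (mm7), at 57818183 to 57818242, 57818408 to 57818467 and 57818511 to 57818570. Its signal in the null pools was 39.2%, 30.8% and 30.2% of the wild-type mean on these probes, in the same order. The differences were -1.35 ± 0.15, -1.70 ± 0.17 and -1.73 ± 0.18 (SE, log2), with limma adjusted p of 0.00614, 0.00460 and 0.00542 over all probes kept. On the brightest probe, the signal fell from 3.37 ± 0.08 to 2.02 ± 0.31 (SD, n = 4 in each group, log2). Null pool 4 stood above the other null pools on all 3 probes, at 54.2%, 44.0% and 45.1% of the wild-type mean, while null pools 1 to 3 lay between 25.0% and 36.1%. The remaining signal was not absent in any null pool, and whether these probes lie in the deleted part of the gene is not given in the sources used here. Within slide 1 alone the difference on the brightest probe was -1.52, and within slide 2 it was -1.18, with limma adjusted p of 0.153 and 0.183 from 2 pools per group. With slide as a block the adjusted p was 0.00703.

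**Figure D1:**
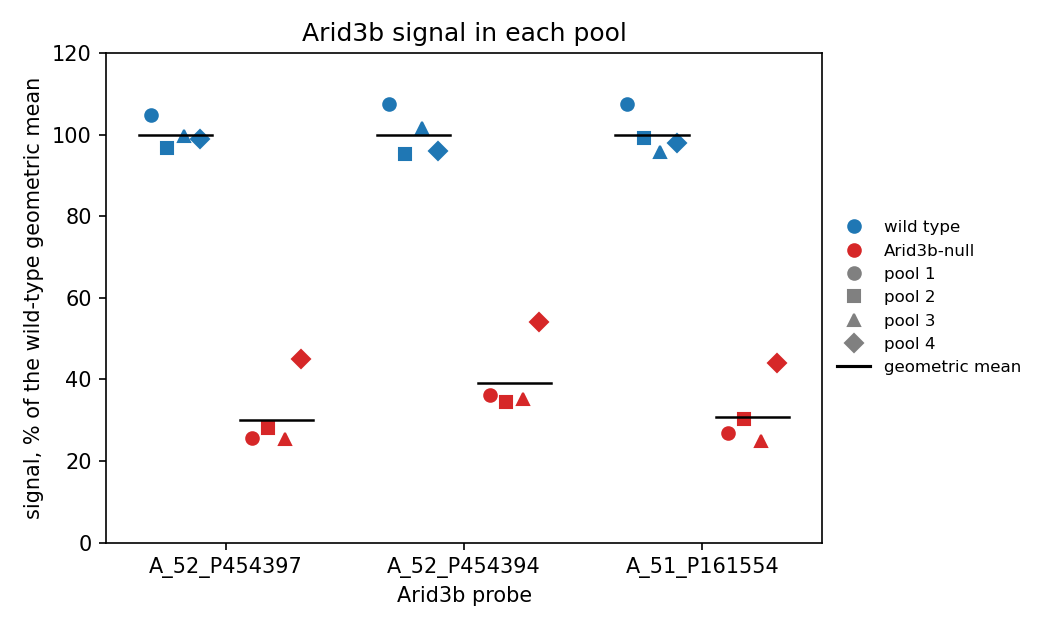
Arid3b signal of each pool on its 3 probes, as a percentage of the wild-type geometric mean, with symbols for the pool number, colours for the genotype and bars for the geometric mean of 4 pools. Null pool 4 lies at 44.0% to 54.2% and the other null pools at 25.0% to 36.1%.

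Of 17099 genes tested, 718 differed between null and wild-type embryos at a limma adjusted p under 0.05. Higher signal in the null pools was seen for 487 of them and lower signal for 231, so that 67.8% rose. At least 2-fold differences were seen for 112 genes, of which 94 rose and 18 fell. All 718 genes had null values that did not overlap the wild-type values. Over all genes tested 16.1% had such separate groups, against 2.86% by chance. The count depended on the arrays used. Fits without a pool had genotype as the only term and slides unequal between the groups, so the slide as well as the smaller number of arrays may lower them. The count was 101, 159, 186 and 93 without wild-type pools 1, 2, 3 and 4, and 326, 418, 114 and 628 without null pools 1, 2, 3 and 4. With the replicate number as a block it was 2321 (1318 higher and 1003 lower), and with slide as a block 1361. Within either slide alone, with 2 pools per group, limma called 0 genes, with 1879 genes at an unadjusted p under 0.05 on slide 1 and 2864 on slide 2. With the level of Y-linked transcripts as a covariate the count was 151, and under normexp background correction limma called 0 genes, with 740 at an unadjusted p under 0.05. Normexp left a raised floor in wild-type pool 4 and null pool 4, with 10th percentiles of log2 signal of 9.88 and 9.12. On the other arrays these were 6.11 to 7.28. The uneven floor limits every normexp value given here. Scaling on the median gave 204 genes, of which 52.0% rose, and leaving the arrays unscaled gave 157, of which 79.6% rose.

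Among the named genes the largest rise was that of Eno2. This gene, which encodes the neuronal form of the glycolytic enzyme enolase, rose 12.1-fold from -4.26 ± 0.26 to -0.66 ± 0.73 (SD, n = 4, log2; limma adjusted p = 0.00388). Chac1, a glutathione-degrading enzyme induced by amino acid and endoplasmic reticulum stress, rose 10.4-fold (adjusted p = 0.00453). The transcriptional repressor Bhlhe40 rose 8.30-fold and had the smallest adjusted p among the named genes, 2.97e-04. Ier3, an early response gene, rose 7.06-fold, Nrn1, a neuronal surface protein, 6.11-fold and Ndrg1, a hypoxia-induced gene, 5.21-fold. Nupr1, a stress-induced nuclear protein, rose 5.17-fold, the pseudokinase gene Trib3 4.75-fold and the secreted glycoprotein gene Stc1 4.59-fold. Nags, the synthase of N-acetylglutamate, also rose (adjusted p = 0.00175), with no size given because only 2 of its 4 wild-type values were well above background. Creg2 rose 3.94-fold and Ddit4, an inhibitor of mTORC1 signalling, 3.93-fold. Stc1 was well above background in 3 of the 4 wild-type pools. Without the wild-type or null pools in turn, 20 of the 68 other named and called genes kept an adjusted p under 0.05 in all 8 fits. These were Bhlhe40, Ndrg1, Ier3, Vldlr, Nags, Creg2, Bnip3, Ero1a, Ddit4, Ddit3, Eno2, Nrn1, Chac1, Fos, Sesn2, Slc10a4, Stc1, Krt19, Mlc1 and Heyl. A further 38 lost it in 1 to 7 of the fits. Of these, 18 lost it in 7 fits, which were Polk, Idi1, Vax2, Lhx2, Tfap2c, Nhlh1, Jag2, Msmo1, Asb17, Snai2, Klf1, Rrm2, Dhrs3, Dbx1, Chrna3, Rbm45, Nppa and Ccne1. Rarb, Cdon, Rnf43, Lims2, Pkp2, Dppa3 and Nppb lost it in 6 fits, and Ccnd1, Gja5, Jaml, Vxn and Nhlh2 in 5. The call was lost in all 8 for 10 genes, which were Pmaip1, Col18a1, Spem2, Itga8, Sox17, Csf2rb, Dll4, Sox3, Tnfrsf10b and Hhex. These fits had fewer arrays and genotype as the only term. On all arrays, 0 of the named genes lost a call with slide as a block and 1 did with the replicate number.

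The largest falls were smaller. Vax2, a homeobox gene of the ventral eye, fell by 1.66 ± 0.30 (SE, log2; limma adjusted p = 0.0296), Jaml, which encodes a junctional adhesion molecule, by 1.52 ± 0.24, and Rbm45, which encodes an RNA-binding protein, by 1.44 ± 0.31. Jaml lies on chromosome 9, within 20 Mb of Arid3b. Spem2 and Dppa3, a marker of primordial germ cells, also fell (adjusted p = 0.0427 and 0.0285). Each had 1 of 4 null values well above background, so that no size of difference is given. Asb17 fell by 1.15 ± 0.23, the transporter gene Slc10a4 by 1.15 ± 0.14, Mlc1 by 1.12 ± 0.14 and Csf2rb, a cytokine receptor subunit, by 1.09 ± 0.23. Vax2 and Asb17 were each well above background in 3 of the 4 null pools, which limits the size of their falls. Vxn, a neurogenic factor, and Nhlh2, a transcription factor of early neurons, were well above background in all wild-type pools and in none of the null pools. They were at least 1.34-fold and at least 1.58-fold higher in wild type (adjusted p = 0.0236 and 0.0265), where the bound sets the wild-type mean against the higher, on each null array, of the lowest signal well above background and the probe's own signal. Spem2 and Csf2rb lost their call in all 8 fits without a pool.

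Most measured genes of the list of hypoxia and glycolysis rose in the null embryos. Of 29 measured members 19 rose, none fell and 10 did not pass the test, with a list median of 0.81. Adjusted over the list alone, 24 were higher and 1 was lower. Besides Bhlhe40, Ndrg1 and Ddit4, the mitophagy gene Bnip3 rose 2.63-fold (1.39 ± 0.11, SE, log2; limma adjusted p = 0.00220) and the oxidoreductase gene Ero1a, which acts in disulphide formation, 2.21-fold (adjusted p = 0.00294). The angiogenic factor Vegfa rose 1.76-fold (adjusted p = 0.0161), the vasodilator peptide gene Adm 3.49-fold (adjusted p = 0.00669) and the glucose transporter gene Slc2a3 1.72-fold (adjusted p = 0.0191). Of the glycolytic enzymes in the list Aldoc rose 2.52-fold, as did the regulators Pfkfb3 and Pdk1, by 1.81-fold and 1.82-fold, while Ldha stood at 0.25 ± 0.11, Pgk1 at 0.32 ± 0.09 and Eno1 at 0.17 ± 0.11 (SE, log2; adjusted p = 0.241, 0.0799 and 0.468). The mean of the list lay at 2.35 to 2.40 in the wild-type pools and at 3.05 to 3.45 in the null pools, a difference of 0.91 against a wild-type SD of 0.02. Camera gave the list an adjusted p of 6.95e-23, and the adjusted p was 0.146 with an estimated correlation. The exact permutation test of the list mean gave a two-sided p of 0.0286, the smallest that 4 against 4 arrays allow, and 0.0857 after adjustment over the 33 lists. With exchange within same-numbered pairs only, 16 arrangements allow no exact p under 0.125, which is the value of this list. The list median was 1.02 within slide 1, 0.65 within slide 2 and 0.81 with slide or replicate number as a block.

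**Figure D2:**
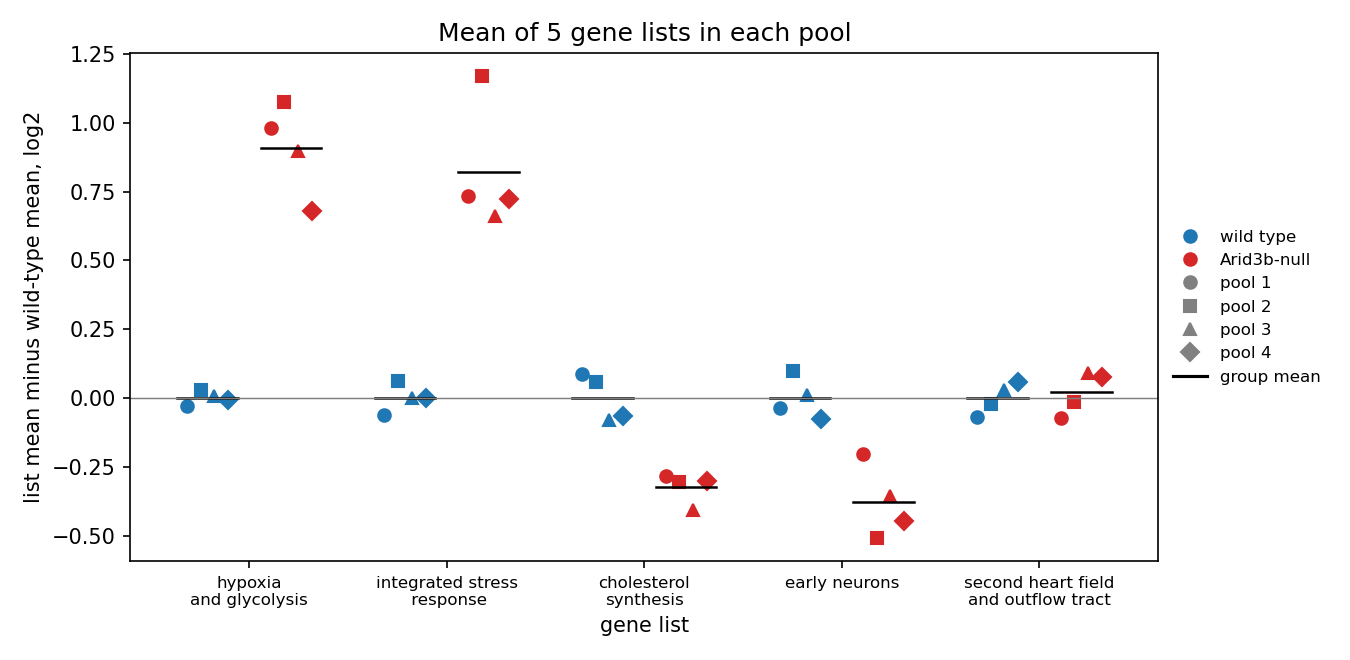
Mean log2 value of 5 gene lists in each pool, relative to the mean of the 4 wild-type pools, with symbols for the pool number, colours for the genotype and bars for the group mean. The 4 null pools lie above all wild-type pools for hypoxia and glycolysis, where the group difference is 0.91, and overlap them for the list of the second heart field and outflow tract.

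Some genes of the integrated stress response also rose. The list covers the transcription factor gene Atf4, targets of it and other stress genes such as Hspa5. Of its 19 measured members 8 rose, none fell and 11 did not pass the test (9 higher adjusted over the list alone). Its median was 0.41, with a camera adjusted p of 4.35e-08 and an adjusted p of 0.308 with an estimated correlation. Next to Chac1, Trib3 and Nupr1, the lipoprotein receptor gene Vldlr rose 3.79-fold (limma adjusted p = 0.00175), the transcription factor gene Ddit3 3.01-fold (adjusted p = 0.00388) and Sesn2 1.91-fold (adjusted p = 0.00657). Atf4 itself stood at 0.05 ± 0.11 and the chaperone gene Hspa5 at -0.12 ± 0.11 (SE, log2). The list median was 0.46 within slide 1, 0.33 within slide 2 and 0.39 with slide as a block. Of 23 targets of p53 and apoptosis genes, 4 rose and none fell over all genes or adjusted over the list alone. Sesn2 is also a member of this list, and Polk, Pmaip1 and Tnfrsf10b rose 1.42-fold, 1.62-fold and 1.84-fold. The list itself did not pass camera (adjusted p = 0.0730). It passed with quantile normalization (adjusted p = 0.0405), with no shift between arrays (0.0395), with the deposited value table (0.0363) and without wild-type pool 3 (0.0117), and Pmaip1 and Tnfrsf10b lost their call in all 8 fits without a pool. Tnfrsf10b had an adjusted p of 0.0651 with the replicate number as a block. Among 18 measured immediate early genes, Ier3 and Fos rose (6 higher adjusted over the list alone), none fell, and the list median was 0.18. Camera gave an adjusted p of 0.00351, against an adjusted p of 0.146 with an estimated correlation. Fos rose 1.88-fold (limma adjusted p = 0.00467). It stood at -0.054 under normexp background correction, and the list's camera adjusted p was 0.219 without the filter on dim probes.

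Genes of cholesterol synthesis had lower means in the null embryos, and a few of them fell. All 19 measured members had a lower mean, of which 4 fell over all genes tested and 10 adjusted over the list alone, and the list median was -0.34. Cyp51, the lanosterol demethylase, fell by 0.58 ± 0.08 (SE, log2; limma adjusted p = 0.0132), Idi1, an isomerase of isoprenoid synthesis, by 0.45 ± 0.08 and Msmo1, a sterol oxidase, by 0.45 ± 0.09. Camera gave the list an adjusted p of 3.30e-09, and the adjusted p was 0.146 with an estimated correlation. The median was -0.37 within slide 1 and -0.30 within slide 2, and -0.34 with slide as a block. Of 25 genes of S phase and mitosis, 2 fell (3 adjusted over the list alone) and none rose. Ccne1, a cyclin of the entry into S phase, fell by 0.39 ± 0.09 and Rrm2, a subunit of ribonucleotide reductase, by 0.41 ± 0.08 (limma adjusted p = 0.0447 and 0.0413), and each lost its call in 7 of the 8 fits without a pool. The list median was -0.09, with a camera adjusted p of 0.00419 and an adjusted p of 0.373 with an estimated correlation. The median was -0.15 within slide 1 and -0.06 within slide 2 (camera adjusted p = 0.0884). Under normexp it was -0.02 (adjusted p = 0.435).

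Some genes of early neurons and of the patterned neural tube fell in the null embryos, and most members of both lists did not pass the test. Among 23 genes of early neurons 4 fell and 1 rose, and adjusted over the list alone 7 were lower and 1 was higher. Nhlh1, a transcription factor of newly formed neurons, fell by 0.80 ± 0.15 (SE, log2; limma adjusted p = 0.0331). Nhlh2, described above, the neurogenic factor gene Neurod4 and the acetylcholine receptor subunit gene Chrna3 were well above background in all wild-type pools and in none of the null pools. Neurod4 and Chrna3 were at least 1.31-fold and at least 1.06-fold higher in wild type, with adjusted p of 0.0132 and 0.0431. Chrna3 lies within 20 Mb of Arid3b. The Notch ligand gene Dll4 rose 1.28-fold (adjusted p = 0.0437). It is also a gene of vessels and a member of the Notch list, and lost its call in all 8 fits without a pool. The median of the early neuron list was -0.29, with a camera adjusted p of 6.98e-05 and an adjusted p of 0.146 with an estimated correlation. It was -0.47 within slide 1 and -0.30 within slide 2. Of 25 genes that pattern the neural tube 4 fell, none rose and 21 did not pass the test, and adjusted over the list alone 7 were lower and 2 higher. Olig2, a factor of motor neuron progenitors, fell by 0.69 ± 0.10 and Dbx1, of ventral interneuron progenitors, by 0.65 ± 0.14. Sox3, a gene of neural progenitors, fell by 0.54 ± 0.12 and Lhx2, of the forebrain and eye, by 0.44 ± 0.08 (adjusted p = 0.0153, 0.0431, 0.0444 and 0.0304). Of the 8 fits without a pool, Olig2 lost its call in 4, Dbx1 and Lhx2 in 7 and Sox3 in 8. The list median was -0.17, with a camera adjusted p of 0.00520 and an adjusted p of 0.394 with an estimated correlation. It was -0.19 within slide 1, -0.10 within slide 2 (camera adjusted p = 0.0598) and -0.14 with slide as a block, and with the level of Y-linked transcripts as a covariate the camera adjusted p was 0.0862.

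The list of the second heart field and outflow tract, the progenitors that lengthen the heart tube, held no called gene. All 24 members were measured, and limma called 0 over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05. The median was 0.02 with a camera adjusted p of 0.679. The smallest p in the list was that of Fgf10, a growth factor of the second heart field, at 0.34 ± 0.09 (SE, log2; limma adjusted p = 0.0803), which became 0.0343 with the replicate number and 0.0468 with slide as a block. Isl1, the marker of this field, stood at -0.19 ± 0.09 (adjusted p = 0.290). Of 25 contractile and chamber genes of cardiomyocytes 2 rose and none fell (3 higher adjusted over the list alone), with a list median of 0.22. The natriuretic peptide genes Nppa and Nppb, which are known both as chamber markers and as stress-responsive genes, rose 2.54-fold and 3.02-fold (adjusted p = 0.0433 and 0.0397, lost in 7 and 6 of the 8 fits without a pool). Null pool 2 was highest for each. The contractile genes Myh6 and Tnnt2 stood at 0.26 ± 0.18 and 0.20 ± 0.07. Camera gave the list an adjusted p of 3.99e-05, and the adjusted p was 0.373 with an estimated correlation. The median was 0.30 within slide 1 and 0.13 within slide 2. In the list of the atrioventricular canal and cardiac patterning 1 of 19 members fell, over all genes and adjusted over the list alone. This was Gja5, a gap junction protein of the atria and arteries, by 0.63 ± 0.10 (adjusted p = 0.0197). The camera adjusted p of that list was 0.269.

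Genes of primitive erythroid cells had lower means, and those of the endothelium did not pass the test as a list. All 18 genes of primitive erythroid cells had a lower mean in the null pools. The list mean of null pool 4, at 1.03, lay above those of wild-type pools 3 and 4, at 0.97 and 1.01, and the exact permutation p was 0.0857. Only Klf1, the erythroid transcription factor, fell over all genes tested, by 0.88 ± 0.18 (SE, log2; limma adjusted p = 0.0377, lost in 7 of the 8 fits without a pool), and 7 fell adjusted over the list alone. The embryonic globins Hbb-bh1 and Hba-x stood at -0.05 ± 0.22 and -0.22 ± 0.23. The list median was -0.38, with a camera adjusted p of 1.27e-05 and an adjusted p of 0.394 with an estimated correlation. It was -0.52 within slide 1 and -0.23 within slide 2. Of 10 measured genes of macrophages and myeloid cells limma called 0 in either count (2 at an unadjusted p under 0.05), the list's camera adjusted p was 0.574, and the smallest p was that of Csf1r (limma adjusted p = 0.109, with 2 of 4 null values well above background, and 0.0373 with the replicate number as a block). In the list of the endothelium and endocardium 1 of 21 members rose, the endodermal and arterial factor gene Sox17, by 1.25-fold (adjusted p = 0.0431, lost in all 8 fits without a pool), and adjusted over the list alone 1 was higher and 1 lower. The list median was 0.13 with a camera adjusted p of 0.0787, which was 0.0285 with the replicate number as a block, 0.0264 without wild-type pool 1, and 0.0355 and 0.0469 without null pools 2 and 4. It also passed under normexp (0.00425), with quantile normalization (0.0361), with the deposited value table (0.0363) and with the Y-linked covariate (0.00579).

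A few epithelial and matrix genes rose, and most members of both lists did not pass the test. In the list of surface ectoderm and epithelium 2 of 21 members rose and none fell (6 higher adjusted over the list alone). Krt19, a keratin of simple epithelia, rose 2.22-fold (limma adjusted p = 0.00805) and Tfap2c, an ectodermal transcription factor, 1.33-fold (adjusted p = 0.0324). The median was 0.25, with a camera adjusted p of 1.27e-05 and an adjusted p of 0.372 with an estimated correlation. It was 0.22 within slide 1 and 0.30 within slide 2. Of 28 genes of the extracellular matrix 2 rose and none fell, in both counts. The proteoglycan gene Dcn rose 1.70-fold (adjusted p = 0.0120) and the basement membrane collagen gene Col18a1 1.26-fold (adjusted p = 0.0424, lost in all 8 fits without a pool). The median was 0.18, with a camera adjusted p of 0.00176 and an adjusted p of 0.422 with an estimated correlation. It was 0.16 within slide 1 and 0.18 within slide 2, and the camera adjusted p was 0.1 without the filter on dim probes. The list of BMP and TGF-beta response had a median of 0.18, with a camera adjusted p of 9.27e-05 and an adjusted p of 0.146 with an estimated correlation. None of its 20 members was called by limma over all genes, with 9 at an unadjusted p under 0.05. Adjusted over the list alone 4 were higher. The smallest p was that of the BMP antagonist gene Grem1, at 0.54 ± 0.13 (adjusted p = 0.0557), which became 0.0282 with the replicate number and 0.0345 with slide as a block. Its list median was 0.23 within slide 1 and 0.18 within slide 2. Of 30 genes of cadherins, junctions and integrin adhesion 3 rose and none fell, in both counts. These were the integrin-linked adaptor gene Lims2 by 1.61-fold, the desmosomal gene Pkp2 by 1.27-fold and the integrin gene Itga8 by 1.37-fold. Of the 8 fits without a pool, Lims2 and Pkp2 lost their call in 6 and Itga8 in 8. That list did not pass camera (adjusted p = 0.232), but did without null pool 2 (adjusted p = 0.0355), under normexp (0.0260) and with the level of Y-linked transcripts as a covariate (0.00579).

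The remaining lists did not pass camera. In the neural crest list 1 of 20 genes rose (3 higher and 2 lower adjusted over the list alone), the factor gene Snai2 by 1.35-fold, and the camera adjusted p was 0.156. In the list of pharyngeal arch mesenchyme and endoderm, with 18 genes, Pax1, a factor of the pharyngeal pouches, fell by 0.93 ± 0.13 and Hhex rose 1.33-fold, over all genes and adjusted over the list alone (camera adjusted p = 0.162, against 0.0181 without the filter on dim probes). Krt19, Sox17 and Hhex made up the 3 of 14 gut endoderm genes that rose in both counts. Sox17 and Hhex lost their call in all 8 fits without a pool, and the camera adjusted p was 0.135 against 0.0370 without null pool 2. In the limb bud list of 20 genes Lhx2 fell in both counts (camera adjusted p = 0.668). The list of presomitic mesoderm and somites had no called gene among 21 in either count (limma, 4 at an unadjusted p under 0.05), a median of -0.15 and a camera adjusted p of 0.107, against 0.0298 without wild-type pool 1, 0.0192 without null pool 4, 0.0122 without the filter on dim probes, 0.0291 within slide 1 and 0.0205 with the Y-linked covariate. The smallest p there was that of Meox2, at -0.28 ± 0.08 (SE, log2; limma adjusted p = 0.0887, and 0.0456 with the replicate number as a block). Among 15 posterior Hox genes limma called 0 in either count (1 at an unadjusted p under 0.05), with a camera adjusted p of 0.924. The list mean varied more between wild-type pools, with an SD of 0.40, than between the groups, and Hoxb9 had the smallest p at 0.21 ± 0.09 (adjusted p = 0.229).

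Lists of extraembryonic tissues differed between the groups by less than the spread between pools. The list of the yolk sac and secreted plasma proteins had 0 of 19 genes called by limma in either count, and 0 at an unadjusted p under 0.05, with a camera adjusted p of 0.347. Its mean per array had an SD of 0.46 in wild type and 0.66 in null pools, Soat2 had the smallest p at 0.31 ± 0.19 (SE, log2; limma adjusted p = 0.415), and without null pool 4 the camera adjusted p was 0.0120. The list of trophoblast, placenta and decidua had 0 of 9 measured genes called in either count (2 at an unadjusted p under 0.05) and a camera adjusted p of 0.519, with Ascl2 at 0.54 ± 0.20 (limma adjusted p = 0.173). Among signalling lists, FGF response had 0 of 17 genes called in either count (3 at an unadjusted p under 0.05, camera adjusted p = 0.170, or 0.0213 under normexp), with Spred1 at 0.27 ± 0.10 (limma adjusted p = 0.178). In the Wnt list of 16 genes Ccnd1, a G1 cyclin, fell by 0.48 ± 0.07 and the receptor regulator gene Rnf43 rose 1.40-fold, with 2 higher and 1 lower adjusted over the list alone and a camera adjusted p of 0.188. In the Hedgehog list Cdon, a co-receptor gene, rose 2.47-fold, as 1 of 14 genes in both counts. Cdon lies on chromosome 9, outside the 20 Mb around Arid3b but within 40 Mb of it. It lost its call in 6 of the 8 fits without a pool. The list's median was -0.09 and its mean difference 0.02 (camera adjusted p = 0.729). In the Notch list of 15 genes the target gene Heyl fell by 1.04 ± 0.14 and the ligand genes Jag2 and Dll4 rose 1.61-fold and 1.28-fold. Adjusted over the list alone 2 were higher and 4 lower, the median was 0.03, the mean difference -0.06, and the camera adjusted p 0.631. Rarb, a retinoic acid receptor, and Dhrs3, a retinaldehyde reductase, rose 1.3-fold and 1.56-fold in the list of retinoic acid response, as 2 of 17 genes (4 adjusted over the list alone), with a camera adjusted p of 0.156. In the ARID family 0 of 12 genes were called by limma (2 at an unadjusted p under 0.05), 1 was higher adjusted over the list alone, and the camera adjusted p was 0.203, against 0.00820 without null pool 2, 0.0154 under normexp, 0.0445 with array weights and 0.0182 with the Y-linked covariate. Jarid2 was closest, at 0.37 ± 0.08 (adjusted p = 0.0537, against 0.0292 with the replicate number and 0.0421 with slide as a block).

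**Figure D3:**
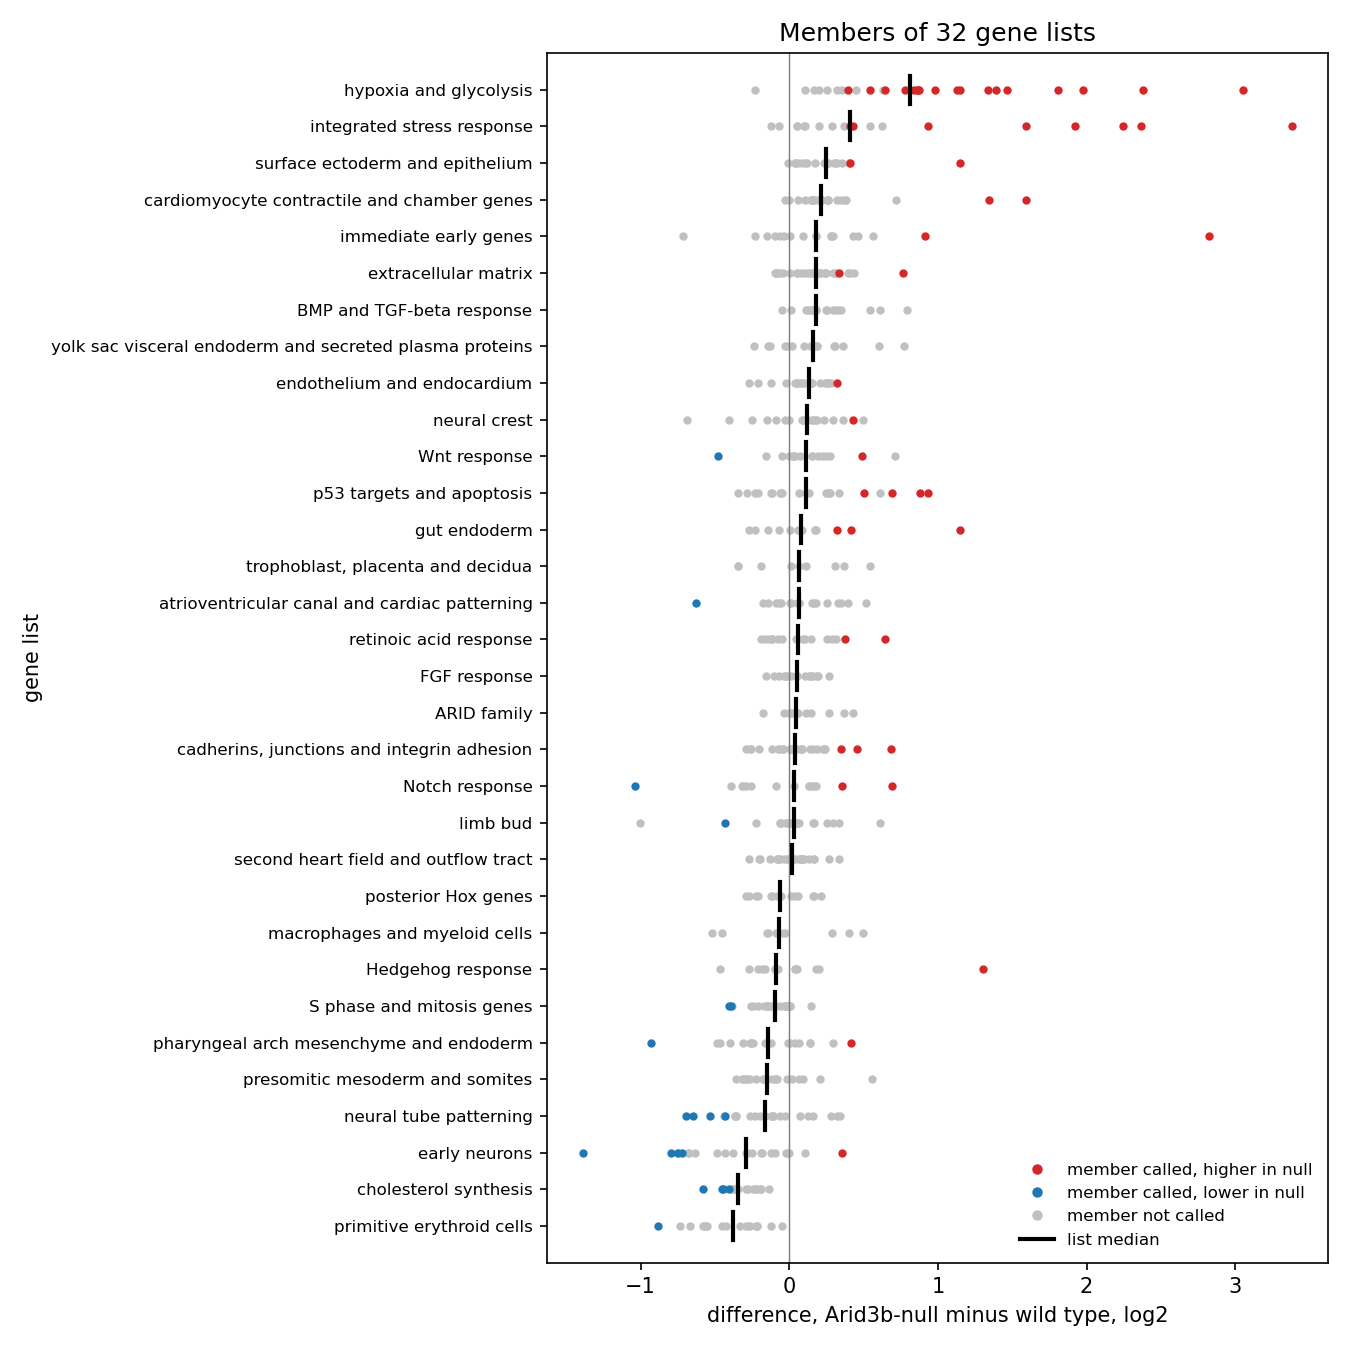
Differences between null and wild-type embryos, in log2, for the measured members of 32 of the 33 gene lists, sorted by list median, with the sex-linked list left out; each point is a gene, red or blue where called at a limma adjusted p under 0.05, and black bars mark list medians. The list of hypoxia and glycolysis has the highest median, 0.81, and that of primitive erythroid cells the lowest, -0.38.

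Genes close to Arid3b were called more often than genes elsewhere. Within 20 Mb of it on chromosome 9, 31 of 369 tested genes were called (8.40%), against 679 of 16460 genes elsewhere (4.13%). The odds ratio was 2.13 by Fisher's exact test, two-sided (p = 3.12e-04), with Arid3b itself left out. Of these 31 genes 19 rose and 12 fell. Jaml and Chrna3, named above, are among them. So is an unnamed transcript next to Jaml, with a difference of -1.50 against -1.52 for Jaml (log2). The entries are thus not all independent, as the exact test takes them to be, and its p may be too small. Windows of 10 and 40 Mb gave odds ratios of 1.95 and 2.03. By the same exact test the odds ratio was 2.06 without wild-type pool 4 (p = 0.140), 2.12 without null pool 3 (p = 0.0973) and 3.44 without wild-type pool 1.

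**Figure D4:**
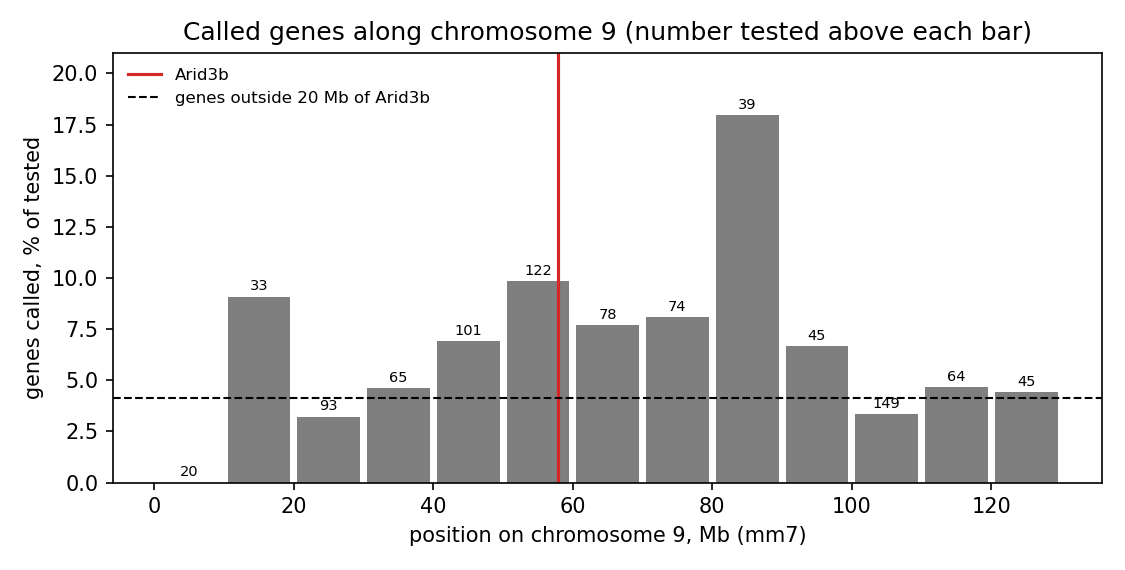
Share of tested genes that were called, in percent, in bins of 10 Mb along chromosome 9 (mm7), with the number of genes tested above each bar, a red line at Arid3b and a dashed line at the 4.13% of genes outside 20 Mb of it. The bin from 50 to 60 Mb, which holds Arid3b, reaches 9.84%, and the bin from 80 to 90 Mb, with 39 genes, reaches 17.9%.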

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

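The tests of the explanations in this part were chosen after the Arid3b values of null pool 4 were seen, and the rule for reading the mixture test was tightened after its value was seen. For 81 probes and genes and 33 list means, each group of 4 pools was searched for a pool whose gap to the nearest other pool took more of the group's range than Dixon's 95% critical value allows. This was met in 12 of 228 groups, and chance gives about 1 in 20.

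Null pool 4 stood apart on the Arid3b probe A_52_P454394, with a ratio of gap to range of 0.903 and a log2 value of 2.48 against 1.83 to 1.89 in the other null pools. On all 3 Arid3b probes pool 4 lay over 3 SD above the other null pools, at 4.98 to 19.4 SD, which argues against a failed spot or probe on that array. Arid3b itself lay in pool 4 22.9% to 29.2% of the way from the other null pools to wild type. Genes within 20 Mb of Arid3b that were called without pool 4 lay in it a median of 33.12% of the way to wild type (95% bootstrap interval 22.2% to 44.3%, 29 genes). For null pools 1 to 3, each left out in turn, the median was 13.5% (-17.3% to 30.9%, 19 genes), 0.553% (-22.3% to 21.3%, 21 genes) and -1.54% (-16.9% to 9.08%, 5 genes). Their starting point, the mean of the other null pools, includes pool 4, which lowers these shares if pool 4 is shifted towards wild type. Arid3b gave -8.82%, -12.4% and -11.1% for them, so pools 1 to 3 are not a like control. The bootstrap intervals resample genes within 1 pool, take the genes as independent and do not measure the spread between pools. Some wild-type or heterozygous RNA in pool 4 may be present, although the interval of pool 1 overlaps that of pool 4. Called genes on other chromosomes lay in pool 4 41.3% of the way and called hypoxia genes 46.2%, more than Arid3b itself. For null pools 1 to 3, with pool 4 in the starting point, the shares were 14.4%, -30.7% and 7.03% on other chromosomes. For hypoxia genes they were -21.5%, -37.2% and 9.93%. Genes chosen as called without a pool may lie nearer to wild type in it through that choice, to which Arid3b was not subject. A milder effect of the genotype in the embryos of pool 4 stays open.

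The other pools that stood apart are given as values. In the null group pool 2 was highest for Nppa (ratio 0.946, 5.14 against 3.88 to 3.95) and Nppb (0.838, 2.06 against 0.46 to 0.72) and for the mean of the immediate early genes (0.835, 0.60 against 0.50 to 0.52) and of the integrated stress response (0.857, 1.88 against 1.38 to 1.45). Null pool 3 was lowest for the mean of cholesterol synthesis (0.835, 1.78 against 1.88 to 1.90). In wild type, pool 1 was lowest for the mean of presomitic mesoderm and somites (0.869), pool 2 was highest for Neurod4 (0.840) and Soat2 (0.863), pool 3 was lowest for Gja5 (0.878) and highest for Jarid2 (0.860), and pool 4 was lowest for Pax1 (0.852).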

How the results depend on the processing

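The alternatives within slides, with Y-linked level and without genes near Arid3b, and every alternative of the calls near Arid3b except the window, were added after the data were seen. The cause of a change was not tested except where stated. The 718 called genes became 0 under normexp (740 at an unadjusted p under 0.05), where the 10th percentile of log2 signal was 9.88 and 9.12 in wild-type pool 4 and null pool 4 and 6.11 to 7.28 on the other arrays. This uneven floor limits normexp as a check. With other settings the count also moved. The called genes became 204 with a median shift, 157 with no shift, 164 without a filter on dim probes, 462 with the deposited value table, 1463 with array weights, 2321 with the replicate block (708 shared), 1361 with the slide block (713 shared), 0 within slide 1, 0 within slide 2, 151 with the Y-linked covariate, 1487 at an adjusted p under 0.1 and 112 at 2-fold or more. Without a pool the count was 93 to 628. It stayed within 1.5 times under the other alternatives, at 671 to 837. Arid3b kept its direction throughout. Its call was lost under normexp (-1.34, adjusted p = 0.216) and within slides 1 and 2 (-1.52 and -1.18). Without a pool its difference was -1.51 to -1.29. The 12 called lists became 0 with camera at an estimated correlation (5 at an unadjusted p under 0.05) and 9 with fry (8 shared; cardiomyocyte, erythroid, neural tube and matrix lists lost at adjusted p of 0.0713, 0.0713, 0.0522 and 0.174, retinoic acid gained at 0.00848), and 10 to 16 under the others, 12 to 16 without a pool. The odds ratio near Arid3b was 2.06 to 3.44 without a pool and 1.87 to 4.01, past the threshold, under the other alternatives it was computed for, which leave out the looser threshold and the 2-fold minimum, and it has no value where no gene was called. Of 78 other named genes under 25 alternatives, 696 values lost a call, 17 gained it and 1 reversed, that of Fos at -0.054 under normexp. Of the list values 6 lost a call, 33 gained it and 0 reversed. Among the named genes and lists, the replicate block changed no call beside the endothelium list and the genes whose values with that block are given above. Dim signal limits Neurod4, Nhlh2, Vxn and Chrna3 to bounds. The scan block was not run, since scan and slide coincide.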

Other observations

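The tests on sex, stage and flanking sequence below were chosen after the results they bear on were seen, and those on sex and flanking sequence replaced earlier ones that had been seen, a difference between wild-type pools that differ in sex, 0.0446 over members with complete values, and the odds ratio of 2.13. The tests on scaling, probe disagreement, brightness and other splits were chosen before.

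Genes near Arid3b on chromosome 9 include several that are not in any of the lists. Aph1b, a subunit of gamma-secretase, fell by 0.78 ± 0.08 (SE, log2; limma adjusted p = 0.00427) and Dis3l, which encodes an exosome ribonuclease, by 0.72 ± 0.07 (adjusted p = 0.00494). Chrna5, an acetylcholine receptor subunit next to Chrna3, rose 1.51-fold (adjusted p = 0.00525), the nuclear receptor gene Rora 3.61-fold (adjusted p = 0.0235) and Anxa2, a membrane-binding protein, 1.96-fold (adjusted p = 0.0158). The glycolytic enzyme gene Pkm also lies in this window and rose 1.29-fold (adjusted p = 0.0429). These 6 genes were chosen after their values were seen.

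The count of called genes was compared with that of other splits of the arrays. Over genes with complete values the real grouping called 712 genes, and 2 of the 35 splits of the 8 arrays into 4 and 4 gave as many, so the full set of splits does not exclude chance. The highest other split, at 1598 genes, is the split by slide, which points to a structure of the samples that calls more genes than genotype does, and with slide as a block 1361 genes were called. The first principal component, with 36.9% of the variance, separates the slides. Among the 8 splits that part all 4 same-numbered pairs, limma called 0 genes at an adjusted p under 0.05 in each split other than the real one, but 8 splits are too few for a share under 0.05.

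The higher signal of hypoxia and glycolysis genes in the null pools was set against 3 technical or compositional explanations. With the level of Y-linked transcripts as a covariate the list median was 0.93, which argues against sex composition. The list mean ranged over only 0.0557 among wild-type pools whose posterior Hox mean ranged over 0.855, so it did not follow Hox level there. Most of that Hox range came from wild-type pool 1, at -2.02 against -1.46 to -1.17 in the others. The Hox difference between the groups, -0.05, also depends on that pool. Early neuron means were lower in every null pool, at -2.44 to -2.14 against -2.01 to -1.83, as a delay could give. Stage is therefore not settled by these values. The lowest median under another scaling or background correction was 0.723, against 0.81 as reported, which argues against unequal scaling. Genotype, stage, position on the slide, which follows genotype, and handling before RNA extraction, for which no value was used here, stay open. No test here tells them apart.

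The calls around Arid3b may come from sequence of the strain of the targeted stem cells that stays linked to the allele. The excess was not confined to the closest genes, with an odds ratio of 2.05 (95% interval 1.3 to 3.12) for genes 2 to 20 Mb away. These are 308 of the 369 genes in the window and hold 25 of its 31 calls, so this nearly repeats the test of the window. The 61 genes under 2 Mb gave 2.54 (0.889 to 5.91), and the rest of chromosome 9 gave 1.28 (0.844 to 1.88). Where the excess ends is not settled. The 40 Mb window gave an odds ratio of 2.03, and 17.9% of the 39 genes from 80 to 90 Mb, outside the 20 Mb, were called. Probes of the same gene disagreed by over 0.5 in log2 for 25 of 144 genes in the window against 552 of 5840 elsewhere, an odds ratio of 2.01 (1.24 to 3.15). Sequence variants under probes, without a change in RNA level, are thus a candidate explanation for part of the calls. The genes were not matched on being called, and the window holds a higher share of called genes. This odds ratio therefore cannot tell such variants from changes in RNA level that probes of a gene report unequally. Brightness is argued against, since 0.02% of 10000 gene sets matched on signal held as many calls. The intervals and this share take neighbouring entries as independent. An effect of Arid3b on its neighbours stays open, and no strain is given in the sources used here.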
